A study of Caenorhabditis elegans with 20 samples.

How the data were processed

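The samples were 5 strains of C. elegans purified for muscle, intestine, neurons, serotonin neurons and dopamine neurons, each with 2 TRAP libraries and 2 whole-animal input libraries, 20 in all. Groups were taken from the labels. According to the submitters' processing notes, reads were aligned with STAR and counted with HTSeq, versions not given in the sources used here, and no genome build is named there. The deposited tables hold 4 kinds of value for each gene and replicate. Per the file headers, the columns called counts hold counts. It was inferred from their values that, within each replicate, the deposited counts of 1 library are whole reads with 1 added. Those of the other are such counts times a factor, which makes them a scaled signal rather than counts. The recovered reads used below undo that factor and rest on this inference. The authors' deposited RPKM is the unit used for every comparison here. The authors' deposited ratio of TRAP over input is the ratio of the scaled signal columns, and it differs from the ratio of RPKM by a factor of 0.278 in neuronal replicate 2 to 1.865 in muscle replicate 2. RPKM was checked to be proportional to the recovered reads. Each deposited replicate table lists only genes with an RPKM of at least 1 in TRAP or input, so a gene absent from a table is low in both, and mitochondrial genome genes are not listed. A few gene names had been turned into dates by a spreadsheet, 11 of 18917 names.

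Recovered reads per library, in the listed genes, ranged from 4.46 M in neuronal input replicate 1 to 239.7 M in dopamine input replicate 1, and the report gives each. The median reads per listed gene were 44 in neuronal input replicate 1 and 70 in neuronal input replicate 2, so low genes are least precise there.

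The design written before the data were examined foresaw an edgeR test on counts and a limma test on normalized values if the files did not hold counts. As the deposited files hold RPKM and scaled counts, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2 of RPKM + 1, on genes listed in both replicates with a mean RPKM of at least 1, with adjusted p by Benjamini and Hochberg at 0.05. TRAP was compared with input in each tissue (n = 2 and 2). The dopamine change was compared with the serotonin change over 8 libraries. Per the file headers the replicates are 2 biological replicates with TRAP and input side by side, so the replicate number was read as a pairing of TRAP and input. The main fit, planned before the data were examined, leaves that pairing out, also in serotonin and dopamine, where it called no gene. A fit with the replicate as a block, which uses the pairing, was run as an alternative. It leaves 1 residual degree of freedom per gene within a tissue (2 without the block), so its p rest mostly on the spread that limma pools over genes. The prior degrees of freedom of that pooling were 6.81 in serotonin and infinite in the other 4 tissues with the block. Without it they were infinite in muscle and neuronal, 568 in intestine, 3.03 in serotonin and 5.97 in dopamine. Where they are infinite, the spread depends on a gene's mean level alone, and disagreement between its own replicates does not enter p or SE. Each ± in the text is the SE of the fit without the block, also where the p beside it is of the fit with the block. The deviations of TRAP and input of the same replicate from their group means correlated at 0.608, 0.603, 0.451, 0.679 and 0.516 in muscle, intestine, neuronal, serotonin and dopamine. The blocked and unblocked counts (serotonin 1425 and 4236 with the block) had been seen before the pairing was settled. p-values measure the spread between these libraries.

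Gene lists were written before the data were examined, 15 of cell type markers and the rest of gene families, 32 in all, of which 31 had tested members. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, for lists of at least 5 tested genes, and counted by gene. The second form rests on the 2 residual degrees of freedom of a tissue, so hardly any list could pass it. For the intestine list in intestine the estimate was -0.0169, yet the camera adjusted p was 0.173 against 1.69e-25. Not passing it therefore decides nothing about a list. Where the estimate was higher, as 0.309 for body wall muscle in muscle, the preset p is likely too small. Lists overlap, so that 25 of the 59 genes of the sperm list are also among the 34 major sperm protein genes, 16 of 24 serotonergic and 7 of 13 dopaminergic genes are in another list, and 21 of 44 epidermis genes are. Overlaps of called genes were tested with Fisher's exact test. Genes were named by a rule, also written before the data were examined. It took the 8 largest increases and 5 largest decreases among genes with an adjusted p below 0.05, at least 10 RPKM in the higher fraction and both TRAP libraries on the same side of both inputs, then the 2 to 4 members of smallest p of each list described, members of a tissue's own list that go against it, and 20 key genes. Of the key genes, sosi-1 was listed in no tissue. Where limma called 0 genes (serotonin, dopamine and their comparison) the first part of the rule was applied to the blocked fit.

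Alternatives were limma with the replicate block, DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood) on recovered reads, RLE scaling of RPKM, a joint fit of all 20 libraries, pseudocounts of 0.1 and 5, no filter, a mean RPKM of at least 5 and leaving out each library in turn. edgeR on these reads, RLE scaling of RPKM and combinations with the block were added after the files were seen. On simulated data of the same size with 200 changed genes, the spread was estimated from the libraries with the replicate as a block and no difference between replicates was put in, so the recovery is an upper guide for the fit without a block. There limma without the block recovered 40 and 44% of 4-fold increases and decreases in muscle (10048 genes), 72 and 84% in intestine (14051), 26 and 10% in neuronal (13435), 62 and 72% in serotonin (14587), 26 and 52% in dopamine (14400) and 24 and 22% in the dopamine to serotonin comparison (14001), with 6 to 19 false calls. Tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 and drawn with matplotlib 3.10.9. As groups hold 2 libraries, no library was tested as an outlier and no regrouping of libraries was run.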

Results

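The series measured messenger RNA attached to ribosomes in chosen cell types of the nematode Caenorhabditis elegans by translating ribosome affinity purification (TRAP), in which ribosomes of one cell type are pulled out of a whole-animal lysate and the transcripts they carry are sequenced. The 5 strains were purified for muscle, intestine, neurons in general (called neuronal here), serotonin neurons and dopamine neurons. Each strain gave 2 TRAP libraries and 2 libraries of whole-animal input RNA, which makes 20 libraries. The animals were L4 larvae grown at 22 °C and collected 46 to 48 h past L1 release. The muscle TRAP libraries held 44.9 and 86.7 M reads (M for mega) in the listed genes, and their inputs held 30.04 and 76.3 M. The intestine TRAP libraries held 87.2 and 139.9 M reads and their inputs 169.9 and 108.6 M. The neuronal TRAP libraries held 136.0 and 52.9 M reads and their inputs 4.46 and 31.5 M. The serotonin TRAP libraries held 28.9 and 165.6 M reads and their inputs 51.9 and 87.7 M. The dopamine TRAP libraries held 56.4 and 162.3 M reads and their inputs 239.7 and 123.5 M.

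Values are RPKM, reads per kilobase of gene scaled to the library, and changes are log2 of TRAP over input on the RPKM + 1 scale, which understates the change of low genes. The median change of all genes was not 0. It was -0.56 in muscle, -0.74 in intestine, 0.81 in neuronal, -0.44 in serotonin and -0.60 in dopamine. Rescaling the libraries by relative log expression (RLE) took -0.44, -0.70, 0.90, -0.35 and -0.54 out of the changes, in the same order. Between the replicates the median change was 0.05 and -1.14 in muscle, -0.51 and -0.95 in intestine, 0.00 and 1.59 in neuronal, -0.50 and -0.37 in serotonin and -0.80 and -0.42 in dopamine.

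**Figure D1:**
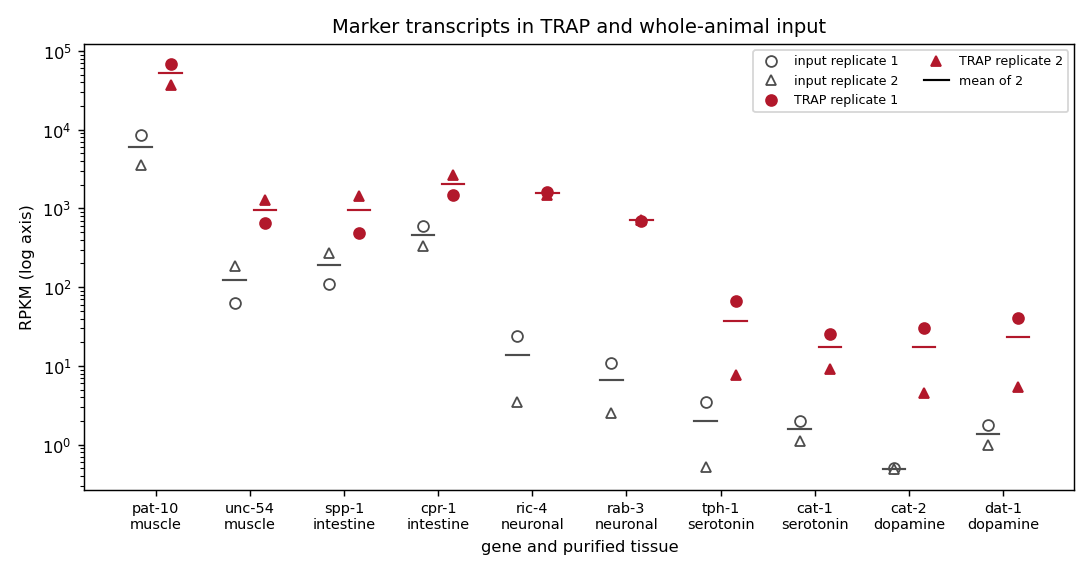
RPKM on a log axis for 10 marker transcripts, each in the purification it belongs to, with open grey symbols for input, filled red symbols for TRAP, circles for replicate 1, triangles for replicate 2 and a bar at the mean of the 2 libraries. In muscle, pat-10 stood at 67814 and 37439 RPKM in TRAP against 8619 and 3547 in input, and in serotonin tph-1 stood at 67.2 and 7.58 against 3.47 and 0.528.

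The muscle purification was set against its input to find the transcripts on ribosomes of muscle cells. The contractile genes mlc-2, pat-10, unc-27, mlc-3 and unc-54 were higher in muscle TRAP than in input. The myosin light chain gene mlc-2 stood at 16761 and 23300.4 RPKM in TRAP against 1316 and 995.5 RPKM in input, a log2 change of 4.11 ± 0.45 (SE, n = 2 and 2 libraries, limma adjusted p = 6.6e-16). The troponin C gene pat-10 reached 67814 and 37439 RPKM against 8619 and 3547, a change of 3.19 ± 0.37 with an adjusted p of 2.89e-14. The troponin I gene unc-27 rose by 3.78 ± 0.49 and the alkali light chain gene mlc-3 by 3.13 ± 0.42. The body wall myosin heavy chain gene unc-54 rose by 3.06 ± 0.69 at an adjusted p of 0.00149. All 5 were above both inputs in both TRAP libraries. mlc-2 is close in sequence to mlc-1, so its reads may be divided between them. Of the 42 tested genes of the body wall muscle list, 24 were higher and 0 lower in TRAP, and 33 were higher when adjusted over the list alone. The median change of the list was 3.15, or 3.62 under RLE (camera adjusted p = 6.07e-82, and adjusted p = 0.522 with an estimated correlation). The other heavy chain of body wall muscle, myo-3, had a change of 2.82 ± 1.02 that did not pass (adjusted p = 0.16, or 0.00152 with the replicate as a block). unc-52, for a basement membrane protein, was the single list member below 0, at -0.06.

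Besides the list, the largest increases in muscle belonged to M02D8.1 (4.37 ± 0.61, adjusted p = 8.77e-10), the profilin gene pfn-3 (4.31 ± 0.69), F40A3.6, the dynein light chain gene dlc-2, the transthyretin-related gene ttr-17, heh-1 and ZK1321.4 (4.003 ± 0.828). Each of these 7 was higher in both TRAP libraries. The largest decreases were in RNAs of other kinds. ZC155.8, R144.15 and B0285.12, annotated as non-coding RNAs, were at 0.316 to 1.97 RPKM in TRAP against 88.9 to 246.2 RPKM in input, with changes of -6.21 ± 1.06, -6.05 ± 1.14 and -5.998 ± 1.208. F23A7.8 changed by -5.55 ± 0.66 (adjusted p = 1.37e-13) and rpr-1, the RNA part of ribonuclease P, by -4.93 ± 1.24 (adjusted p = 0.00663). Major sperm protein genes fell together, 27 of 32 lower and 0 higher (31 lower adjusted over the list alone), at a median of -3.15, or -2.66 under RLE (camera adjusted p = 3.34e-43, and adjusted p = 0.522 with an estimated correlation). Among them msp-36 was at 114.2 and 437.3 RPKM in TRAP against 2842 and 2590.2 in input (-3.59 ± 0.60). The genes msp-152 and msp-31 changed by -3.59 ± 0.68 and -3.25 ± 0.62, although these genes are near copies of each other and single members are uncertain. In the wider sperm list, 26 of 56 were lower and 0 higher (37 lower adjusted over the list alone, median -2.31, camera adjusted p = 2.45e-32, adjusted p = 0.522 with an estimated correlation). Under RLE limma called 15 genes lower in all of muscle, so neither the 27 nor the 26 lower calls can all hold there. Of the intestine list, 3 of 38 were lower and 0 higher, also 3 when adjusted over the list alone, with a median of -1.26, or -0.82 under RLE (camera adjusted p = 9.44e-05, adjusted p = 0.522 with an estimated correlation). The 3 were the metallothionein gene mtl-2 (-3.06 ± 0.78), the intestinal actin gene act-5 (-2.44 ± 0.71) and the saposin-like gene spp-5 (-2.38 ± 0.69).

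Ligand-gated and DEG/ENaC channel genes had a median change of 1.64 in muscle and a camera adjusted p of 1.75e-11 (adjusted p = 0.522 with an estimated correlation), with 0 of 13 passing over all genes and 9 higher adjusted over the list alone. The acetylcholine receptor subunits lev-1 and acr-15 changed by 2.66 ± 0.87 and 1.90 ± 0.64, and both were called only with the replicate block (adjusted p = 0.0142 and 0.0349). Of 80 cytosolic ribosomal protein genes, 0 were higher and 4 lower in muscle (1 and 5 adjusted over the list alone), rla-0, rla-1, rps-12 and rpl-11.1, with changes from -1.39 to -2.12. The list's median of -0.30 turned to 0.20 under RLE (camera adjusted p = 0.0914). The gene of the ribosomal protein rpl-1 changed by 1.26 ± 0.40 in the other direction (adjusted p = 0.0726, or 0.000674 with the block). None of the 17 tested genes of the elongin, cullin and SOCS box list passed in muscle, also adjusted over the list alone, and the list's median of -0.18 turned to 0.31 under RLE (camera adjusted p = 0.418). Its members elb-1, elc-1, cul-2, cul-5, rbx-1 and rbx-2 lay between -0.51 and 0.72 and were not called. Nor were rab-3, snb-1, vit-6 and bas-1, at 0.43, 0.35, 0.01 and -2.10. The genes tph-1, ges-1, cat-2, dat-1, mod-5 and cat-1 were not listed in both muscle replicates.

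In all, limma called 111 genes higher and 95 lower of 10048 tested in muscle. With the replicate as a block it called 328 and 429, a share of higher calls of 43.3% that became 56.5% under RLE. Without the block, RLE gave 288 and 15 where edgeR on recovered reads gave 320 and 14. Leaving out TRAP replicate 1, TRAP replicate 2, input replicate 1 or input replicate 2 left 15, 17, 219 or 174 higher and 4, 18, 1785 or 87 lower genes. Of the 31 called genes named here 23, 18, 4 or 6 then lost the call.

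The intestine purification was compared with its input in the same way. The digestive or antimicrobial genes spp-1, spp-14 and cpr-1 were higher in intestine TRAP. Under RLE spp-1 and spp-14 had larger changes, 3.11 and 3.20, but no longer passed (adjusted p = 0.164 and 0.206), and 0 genes did. The saposin-like gene spp-1, with a product active against bacteria, stood at 491.2 and 1445 RPKM in TRAP against 110.2 and 270.7 in input, a log2 change of 2.28 ± 0.61 (SE, n = 2 and 2 libraries, limma adjusted p = 0.0124). Its relative spp-14 changed by 2.36 ± 0.73 and the cathepsin B-like protease gene cpr-1 by 2.17 ± 0.64 (adjusted p = 0.0273), and all 3 were higher in both TRAP libraries. Of 50 tested genes of the intestine list, 2 were higher (spp-1 and cpr-1) and 0 lower, with 5 higher adjusted over the list alone. With the replicate block, 18 were higher and 2 lower, among the first mtl-2 (1.91 ± 0.65, adjusted p = 0.054, or 5.2e-05 with the block) and the lysozyme gene lys-7 (1.80 ± 0.62, adjusted p = 0.0553, or 0.000623 with the block). The list's median was 1.07, or 1.83 under RLE (camera adjusted p = 1.69e-25, and adjusted p = 0.173 with an estimated correlation). The members below 0 were far-3 (-1.46) and dod-6 (-1.37), both lower with the block at adjusted p of 0.0318 and 0.0226, and ire-1 (-0.46), inx-16 (-0.29), pgp-3 (-0.24), nhx-2 (-0.15) and pept-1 (-0.02), which did not pass. The carboxylesterase gene ges-1 changed by 0.74 and the yolk protein gene vit-6 by 1.22, neither passing at adjusted p of 0.391 and 0.17.

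The remaining largest increases in intestine were in C08E3.13 (2.63 ± 0.59, adjusted p = 0.00134), C08E3.1, T26H5.9, F20E11.17, Y119D3B.21 and F53A9.1 (2.20 ± 0.59), each higher in both TRAP libraries. The histone genes, which include near copies whose reads cannot be assigned with certainty, had 2 of 36 higher, his-17 (1.85 ± 0.59) and his-48 (1.96 ± 0.63), 0 lower and 13 higher adjusted over the list alone, at a median of 1.14, or 1.76 under RLE (camera adjusted p = 1.53e-21, and adjusted p = 0.203 with an estimated correlation). With the block, 14 were higher. Cytosolic ribosomal protein genes had a median of 0.79, or 1.62 under RLE (camera adjusted p = 1.69e-25, and adjusted p = 0.624 with an estimated correlation), yet 0 of 80 passed, also adjusted over the list alone, against 43 higher and 1 lower with the block. The largest was rpl-11.2 (1.82 ± 0.70, adjusted p = 0.0767, or 8.84e-06 with the block), and rpl-1 changed by 0.99 (adjusted p = 0.323, or 0.0194 with the block).

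Some markers of other tissues were called lower in intestine TRAP, where the median of all genes was -0.74 and limma under RLE called 0 genes lower. Of the body wall muscle list, 5 of 45 were lower and 0 higher (24 lower adjusted over the list alone, 26 with the block) at a median of -1.36, or -0.58 under RLE (camera adjusted p = 6.56e-05, and adjusted p = 0.85 with an estimated correlation), with mlc-1 at -2.37 ± 0.61 and the integrin alpha gene pat-2 at -2.17 ± 0.63. Of the epidermis list, 8 of 43 were lower and 0 higher (11 lower adjusted over the list alone, 24 with the block) at a median of -1.27, or -0.46 under RLE (camera adjusted p = 0.00118, and adjusted p = 0.712 with an estimated correlation). They included noah-1, for a cuticle-associated protein (-2.32 ± 0.60), the collagen gene dpy-2 (-2.12 ± 0.59) and the hedgehog-related gene wrt-4 (-2.10 ± 0.60). Pan-neuronal genes had 5 of 28 lower and 0 higher (8 lower adjusted over the list alone), with unc-33 at -2.78 ± 0.56 and rgef-1 at -1.54 ± 0.38, at a median of -0.78, or -0.09 under RLE, that the list test did not set apart from other genes (camera adjusted p = 0.21). The largest decreases were in the fatty acid elongase gene elo-3 (3.67 and 1.11 RPKM in TRAP against 76.1 and 115.1 in input, -4.91 ± 0.63, adjusted p = 3.51e-10), ZC155.8 (-4.70 ± 0.64), Y94H6A.7 (-4.42 ± 0.59), the cap-binding protein gene ncbp-2 (-4.34 ± 0.60) and R144.15 (-4.32 ± 0.62). All were below both inputs in both TRAP libraries.

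Of 17 elongin, cullin and SOCS box genes tested in intestine, 1 was lower and 0 higher, also when adjusted over the list alone. It was elc-1, for elongin C, at 5.57 and 5.08 RPKM in TRAP against 16.04 and 67.0 in input (-2.43 ± 0.64, adjusted p = 0.00967). The median of the list, -0.31, turned to 0.53 under RLE (camera adjusted p = 0.381), and elb-1, cul-2, cul-5, rbx-1 and rbx-2 lay between -1.20 and -0.11 without passing. Among the other key genes unc-54 changed by 0.59, myo-3 by -0.82, rab-3 by -1.13, snb-1 by -0.38, dat-1 by -0.86 and bas-1 by 0.01, none called. tph-1 was not listed in intestine, and cat-1, cat-2 and mod-5 were too low to test.

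limma called 57 genes higher and 750 lower of 14051 tested in intestine, and 317 and 2935 with the replicate as a block. Under RLE it called 0 and 0, and the share of higher calls with the block moved from 9.75% to 67.99%. edgeR on recovered reads called 0 and 0, with 2232 genes at an unadjusted p below 0.05 against 4191 in limma, and DESeq2 called 701 and 280. Without TRAP replicate 1, TRAP replicate 2, input replicate 1 or input replicate 2 there were 20, 6, 124 or 25 higher and 649, 49, 1255 or 209 lower genes. Of the 25 called genes named here 11, 20, 5 or 13 then lost the call, the last of 24 still tested.

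The neuronal purification was compared with its input to find transcripts on ribosomes of neurons in general. Synaptic, neuropeptide and sensory genes were higher in neuronal TRAP by up to 7.19 on the log2 scale. ric-4, the SNAP-25 homolog of synaptic vesicle fusion, stood at 1639 and 1468 RPKM in TRAP against 23.9 and 3.52 in input, a change of 7.19 ± 0.89 (SE, n = 2 and 2 libraries, limma adjusted p = 1.58e-12). rab-3, for a synaptic vesicle GTPase, was at 687.7 and 722.7 RPKM against 10.8 and 2.51 (6.78 ± 0.98, adjusted p = 2.38e-09). Of 30 pan-neuronal genes tested, 26 were higher and 0 lower (29 higher adjusted over the list alone), with a median of 4.43, or 3.72 under RLE (camera adjusted p = 2.64e-21, and adjusted p = 0.487 with an estimated correlation). The 7B2 chaperone gene sbt-1, the complexin gene cpx-1 and the synaptobrevin gene snb-1 rose by 6.40 ± 0.80, 5.81 ± 0.88 and 3.55 ± 0.75. The list members that did not pass were unc-64 (1.86), unc-31 (2.37), ric-7 (2.85) and syd-2 (3.17), all above 0.

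Other large increases in neuronal TRAP were in C33A12.4 (7.14 ± 0.93), Y44A6D.2 (7.10 ± 0.80), H05L03.3 (6.95 ± 0.78), the touch neuron tubulin gene mec-12 (6.93 ± 0.88), C07A12.2 (6.73 ± 1.07) and C39B10.5 (6.72 ± 1.23), each higher in both TRAP libraries. Neuropeptide genes rose in 76 of 99 cases and fell in 0 (78 higher adjusted over the list alone, median 5.17, or 4.105 under RLE, camera adjusted p = 7.49e-48, adjusted p = 0.487 with an estimated correlation), among them nlp-12 (6.61 ± 0.87), ins-28 (6.50 ± 0.91) and flp-24 (6.49 ± 0.80). Ciliated sensory genes were higher in 40 of 43 (42 adjusted over the list alone, median 3.60, or 2.97 under RLE, camera adjusted p = 4.2e-16, adjusted p = 0.487 with an estimated correlation), with the intraflagellar transport gene ift-20 at 5.42 ± 1.30. The transmitter classes moved the same way. Glutamatergic genes were higher in 14 of 14, also adjusted over the list alone, at a median of 3.60, cholinergic genes in 9 of 11 (10 adjusted over the list alone) at 3.96. GABAergic genes were higher in 5 of 7, also 5 adjusted over the list alone, at 3.77. The choline acetyltransferase gene cha-1 was at 5.11 ± 1.32 and the glutamate decarboxylase gene unc-25 at 6.43 ± 0.99. Dopaminergic genes were higher in 9 of 13 (10 adjusted over the list alone) at a median of 3.04 and serotonergic genes in 12 of 21 (17 adjusted over the list alone) at 2.63. The camera adjusted p of these 5 lists was between 8.6e-12 and 0.00041, and between 0.487 and 0.53 with an estimated correlation. Under RLE their medians lay between 2.08 and 3.34.

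Among single transmitter genes, the tyrosine hydroxylase gene cat-2 rose by 4.66 ± 1.30 (adjusted p = 0.00497), the vesicular monoamine transporter gene cat-1 by 3.04 ± 1.14 (adjusted p = 0.0448) and the tryptophan hydroxylase gene tph-1 by 2.13 ± 0.70 (3.57 and 4.96 RPKM against 0.247 and 0.140, adjusted p = 0.0178), each higher in both TRAP libraries. The dopamine transporter gene dat-1 and the amino acid decarboxylase gene bas-1 changed by 3.12 ± 1.22 and 1.16 ± 1.24 without passing (adjusted p = 0.0592 and 0.686). Channel genes rose too, 60 of 85 ligand-gated and DEG/ENaC channels (69 adjusted over the list alone, median 2.86) and 40 of 58 potassium channels (45 adjusted over the list alone, median 3.20), as did 42 of 76 homeobox genes (57 adjusted over the list alone, median 3.11), with 0 lower in each. The POU homeobox gene unc-86 rose by 5.76 ± 1.28, the potassium channel gene kcnl-4 by 4.89 ± 1.33 and the acetylcholine receptor gene acr-12 by 3.90 ± 1.08. The camera adjusted p of the 3 lists was at most 3.61e-09, and 0.53 or 0.634 with an estimated correlation. Under RLE their medians lay between 2.334 and 2.615.

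In the opposite direction, 16 of 80 ribosomal protein genes were lower in neuronal TRAP and 1 was higher (20 and 1 adjusted over the list alone, 30 and 1 with the block) at a median of -1.01, or -2.22 under RLE (camera adjusted p = 2.09e-30, and adjusted p = 0.487 with an estimated correlation). The lower ones included rla-1 (-2.04 ± 0.56) and rps-12 (-1.996 ± 0.5807). The single higher one was rpl-1, at 15411 and 23060.1 RPKM in TRAP against 4219 and 5848 in input (1.92 ± 0.53, adjusted p = 0.00467). Major sperm protein genes were lower in 26 of 32 and higher in 1 (29 and 1 adjusted over the list alone, median -2.63, camera adjusted p = 2.59e-34, adjusted p = 0.487 with an estimated correlation), with msp-36 at -3.16 ± 0.71 and msp-52 the member that rose, by 4.71 ± 1.252, all uncertain as near copies. R144.15, ZC155.8, B0285.12, rpr-1 and F23A7.8 changed by -6.31 ± 1.12, -6.09 ± 1.04, -5.68 ± 1.17, -4.89 ± 1.23 and -4.63 ± 0.80, below both inputs in both TRAP libraries. Of the body wall muscle list, 4 of 45 were higher and 1 lower. Those named by the rule were stn-1, unc-43 and unc-54, with changes of 4.50 ± 1.16, 3.83 ± 0.91 and 2.90 ± 0.87, and pat-10, at -1.91 ± 0.62. The median of that list was 0.08 and its mean 0.47, but camera placed it below other genes (adjusted p = 0.0145, and 0.734 with an estimated correlation) and under RLE the median turned to -0.75. Of the other key genes, vit-6 changed by 0.44 and myo-3 by 0.48 without passing, and ges-1 and mod-5 were not listed in both replicates.

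Of 18 tested genes of the elongin, cullin and SOCS box list, 2 were higher and 0 lower in neurons. These were hif-1, for the hypoxia-inducible factor (3.52 ± 0.94, adjusted p = 0.00379), and elc-2, an elongin C relative (4.14 ± 1.252, adjusted p = 0.00945), both higher in both TRAP libraries. hif-1 is on the list but is a transcription factor gene, not one for an elongin, cullin or SOCS box protein. Adjusted over the list alone, 2 were higher. The median of the list was 1.16, or 0.05 under RLE (camera adjusted p = 0.631), and elb-1, elc-1, cul-2, cul-5, rbx-1 and rbx-2 lay between -0.08 and 1.98 without passing.

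limma called 2257 genes higher and 79 lower of 13435 tested in neurons, or 1383 and 79 under RLE, and the share of higher calls with the replicate as a block moved from 95.8% to 61.5%. edgeR on recovered reads called 0 and 0, with 4106 genes at an unadjusted p below 0.05 against 3416 in limma, and DESeq2 called 2593 and 1013. Without TRAP replicate 1, TRAP replicate 2, input replicate 1 or input replicate 2 there were 513, 1187, 4024 or 457 higher and 5, 8, 135 or 18 lower genes. Of the 45 called genes named here 27, 24, 3 or 20 then lost the call. Input replicate 1 was the shallowest library, at 4.46 M reads.

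**Figure D2:**
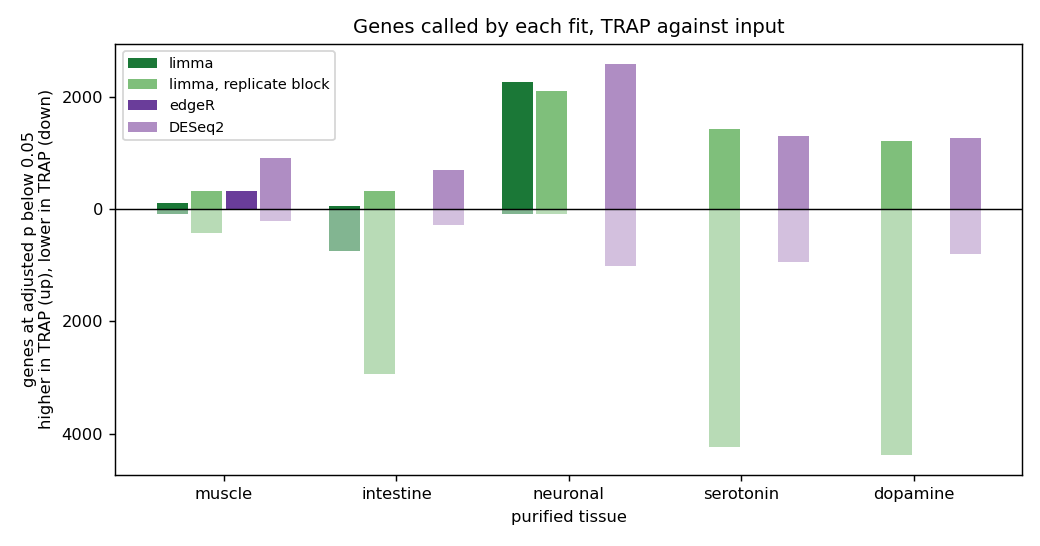
Number of genes at an adjusted p below 0.05 in each purification, higher in TRAP as bars above 0 and lower in TRAP as paler bars below 0, by limma, limma with the replicate as a block, edgeR on recovered reads and DESeq2. limma without the block called 2257 higher genes in neuronal and 0 in serotonin and dopamine, where the block gave 1425 and 1216.

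The serotonin purification asked which transcripts were on ribosomes of serotonin neurons. No gene passed limma without a block (0 higher and 0 lower of 14587, with 4034 at an unadjusted p below 0.05). edgeR also called 0 and 0 (3388 unadjusted). limma with the replicate as a block called 1425 higher and 4236 lower and DESeq2 1304 and 936, so the rule for the largest changes was applied to the blocked fit. Of all calls with the block, 25.2% were higher, against 46.6% under RLE. tph-1, the tryptophan hydroxylase of serotonin synthesis, stood at 67.2 and 7.58 RPKM in TRAP against 3.47 and 0.528 in input (log2 change 3.21 ± 1.12, SE, n = 2 and 2 libraries, limma adjusted p = 0.157, or 0.00449 with the block). The vesicular monoamine transporter gene cat-1 was at 25.1 and 9.23 RPKM against 2.03 and 1.12 (2.69 ± 0.59, adjusted p = 0.00449 with the block). The neuropeptide genes flp-4 and nlp-3 changed by 2.57 ± 0.51 and 1.98 ± 0.39 and the DEG/ENaC channel gene del-3 by 3.55 ± 0.81. All 5 were higher in both replicates. Of 21 tested serotonergic genes, 0 passed over all genes and 4 were higher and 1 lower adjusted over the list alone, while with the block 11 were higher and 3 lower. The median was 1.31 (camera adjusted p = 7.01e-05, and adjusted p = 0.848 with an estimated correlation). The 3 lower with the block were ptps-1 and cat-4, both of cofactor synthesis for the hydroxylases (-2.06 ± 0.36 and -1.55 ± 0.58), and nlp-15 (-1.02 ± 0.53). The members bas-1, egl-44 and egl-46 lay at -0.21, -0.22 and -0.47. The serotonin transporter gene mod-5 changed by 0.72 ± 0.70 and passed neither fit.

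The largest increases with the block in serotonin TRAP were in K07B1.8 (97.2 and 208.5 RPKM against 0.784 and 1.81, 6.002 ± 0.538, adjusted p = 0.000357 with the block), the myosin heavy chain genes myo-3 (5.97 ± 0.45), nmy-2 (5.85 ± 0.40), unc-54 (5.27 ± 0.45) and myo-1 (5.09 ± 0.44), C04E6.8 (5.90 ± 0.80), the pseudogene Y41E3.5 (5.75 ± 0.67) and R102.2 (8447 and 5349 RPKM against 98.6 and 215.4, 5.52 ± 0.54). The largest decreases were in Y18D10A.3 (-4.25 ± 0.37), glb-1, for a globin (-4.24 ± 0.65), C50F2.4 (-4.18 ± 0.67), lin-7 (-4.14 ± 0.76) and F41F3.8 (-4.07 ± 0.39). As a set, the other body wall muscle genes did not move with the myosins, as 44 tested without them had a median of -0.55 and an upper quartile of 0.097. Of the whole list of 46, which holds unc-54 and myo-3, 3 were higher and 1 lower adjusted over the list alone and 4 higher and 13 lower with the block. The median of the whole list was -0.46, or -0.07 under RLE (camera adjusted p = 0.972).

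Cytosolic ribosomal protein genes had a median above 0 in serotonin TRAP. Of 80, 0 passed over all genes, 47 were higher and 0 lower adjusted over the list alone and 46 were higher and 0 lower with the block, at a median of 1.75 (camera adjusted p = 4.12e-24, and adjusted p = 0.848 with an estimated correlation). rpl-24.1 was the largest (3.44 ± 0.48), and rpl-1 changed by 2.77 ± 0.45, at 7623 and 5436 RPKM against 741.5 and 1203 (adjusted p = 0.00569 with the block). Ciliated sensory genes had 10 of 35 higher and 0 lower adjusted over the list alone and 18 and 0 with the block, at a median of 1.247 (camera adjusted p = 1.37e-12, and adjusted p = 0.848 with an estimated correlation), with the ciliary genes dyf-3 and osm-3 at 2.29 ± 0.40 and 2.29 ± 0.46. Pan-neuronal genes were mixed, 4 of 28 higher and 1 lower adjusted over the list alone and 7 and 2 with the block, at a median of 0.30, or 0.68 under RLE (camera adjusted p = 0.00177, and adjusted p = 0.848 with an estimated correlation). The members with the smallest p were egl-3 (3.26 ± 0.40), egl-21 (2.78 ± 0.46), sbt-1 (2.49 ± 0.36) and ida-1 (2.38 ± 0.45), all higher with the block, while rab-3 (0.85) and snb-1 (0.09) passed neither fit. Genes of cytochrome P450 and UDP-glucuronosyltransferase enzymes, which handle foreign and endogenous small molecules, were lower in 48 of 98 and higher in 2 with the block, in 0 adjusted over the list alone, at a median of -0.96 (camera adjusted p = 0.00177, and adjusted p = 0.848 with an estimated correlation), with ugt-62 at -2.50 ± 0.50.

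Elongin, cullin and SOCS box genes went both ways in serotonin TRAP. Of 18, 1 was higher and 1 lower adjusted over the list alone and 3 higher and 4 lower with the block, at a median of 0.08, or 0.46 under RLE (camera adjusted p = 0.312). elc-2 was at 100.7 and 82.2 RPKM in TRAP against 2.12 and 1.53 in input (5.03 ± 0.38, adjusted p = 0.000685 with the block). hif-1, a transcription factor gene on the list and not of these protein families, was higher by 1.10 ± 0.39. The lower ones were elc-1 (-2.16 ± 0.96, adjusted p = 0.00767 with the block), the RING box gene rbx-1 (-1.77 ± 0.37), vhl-1, for the von Hippel-Lindau protein (-1.14 ± 0.40), and the elongin B gene elb-1 (-1.02 ± 0.38, adjusted p = 0.0411 with the block). rbx-2, cul-2 and cul-5 changed by -0.86, 0.29 and -0.36 and passed neither fit. dat-1 changed by -0.72, ges-1 by 0.00 and vit-6 by 1.503 ± 2.581, of which only vit-6 passed with the block (adjusted p = 0.0163), and cat-2 was not listed in both replicates. No call appeared when any of the 4 serotonin libraries was left out (0 higher and 0 lower each time by limma).

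The dopamine purification was compared with its input in the same way. limma without a block called 0 genes higher and 0 lower of 14400 (4015 at an unadjusted p below 0.05) and edgeR 0 and 0 (3403 unadjusted). With the replicate as a block limma called 1216 higher and 4386 lower, and DESeq2 called 1265 and 799. The rule for the largest changes was again applied to the blocked fit. Of the calls with the block, 21.7% were higher, against 51.8% under RLE. The neuropeptide gene flp-33 had the largest change, at 8760.3 and 381.4 RPKM in TRAP against 10.1 and 15.9 in input (log2 change 7.06 ± 1.26, SE, n = 2 and 2 libraries, limma adjusted p = 0.085, or 1.76e-32 with the block). That SE is of the fit without the block, the change was 9.62 in replicate 1 and 4.50 in replicate 2, and the smaller p rests on a spread pooled over genes, as the blocked fit leaves 1 residual degree of freedom. The tyrosine hydroxylase gene cat-2, for the first step of dopamine synthesis, was at 30.5 and 4.57 RPKM against 0.503 and 0.486 (3.15 ± 0.81, adjusted p = 3.19e-08 with the block). The dopamine transporter gene dat-1 was at 41.02 and 5.43 against 1.76 and 0.985 (2.81 ± 0.89) and the mechanosensory channel gene trp-4 changed by 2.14 ± 0.57. These 4 were higher in both replicates. Of 12 tested dopaminergic genes, 0 passed over all genes, 5 were higher and 2 lower adjusted over the list alone and 7 higher and 3 lower with the block, at a median of 1.24 (camera adjusted p = 0.00216, and adjusted p = 0.944 with an estimated correlation). The 3 lower were ptps-1 (-2.80 ± 0.64), cat-4 (-2.64 ± 0.73) and bas-1 (-1.30 ± 0.56), all of monoamine synthesis, and cat-1 was higher by 1.71 ± 0.58.

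Of the myosin heavy chain genes, 6 had changes of 4.67 or more in dopamine TRAP and were called with the block. unc-54 was at 417.9 and 33081 RPKM in TRAP against 23.3 and 145.6 in input (5.96 ± 1.84, adjusted p = 2.58e-11 with the block), which is 20.5% of all reads in TRAP replicate 2. The genes myo-3, myo-2, nmy-2, myo-1 and nmy-1 changed by 5.18 ± 1.82, 5.16 ± 1.38, 5.06 ± 1.48, 4.76 ± 1.39 and 4.67 ± 1.29. The pharyngeal gene myo-5 changed by less, 3.84 ± 1.16 (adjusted p = 3.52e-09 with the block), and myo-6, chosen after its values were seen, by 0.51 ± 0.75 without passing either fit. K07B1.8 changed by 5.28 ± 0.78. The first 6 together took 27.7% of the reads of TRAP replicate 2 and 0.434% of those of TRAP replicate 1. The largest decreases were in mrpl-45, for a mitochondrial ribosomal protein (-4.54 ± 0.57), the adaptor complex gene aps-3 (-4.47 ± 0.74), Y47D3A.21 (-4.16 ± 0.55), Y94H6A.7 (-4.08 ± 0.61) and F40G9.17 (-4.02 ± 0.62).

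Germline genes were higher in dopamine TRAP in 5 of 44 adjusted over the list alone, 0 lower, and in 12 against 4 lower with the block, at a median of 0.48, or 1.07 under RLE (camera adjusted p = 3.54e-05, and adjusted p = 0.944 with an estimated correlation). The egg surface gene egg-1 was at 46.7 and 52.2 RPKM against 3.60 and 4.30 (3.35 ± 0.56), and the oocyte genes mex-5 and oma-2 changed by 2.80 ± 0.61 and 2.60 ± 0.58. Ribosomal protein genes had a median of 1.05, or 1.66 under RLE (camera adjusted p = 2.72e-07, and adjusted p = 0.944 with an estimated correlation), but 0 of 80 passed, also adjusted over the list alone, and 3 with the block. The median was 2.58 in replicate 1 and -0.80 in replicate 2. For these genes replicate 1 minus replicate 2 was 1.861 in TRAP and -1.355 in input, so the inputs disagreed too. The 3 were rps-6 (2.97 ± 1.30), rpl-20 (2.63 ± 1.27) and rpl-25.1 (2.16 ± 0.95), and rpl-1 changed by 1.65 without passing either fit. Neuropeptide genes were lower in 62 of 96 and higher in 4 with the block (5 and 1 adjusted over the list alone), at a median of -1.39, or -0.83 under RLE, against -0.60 for all genes without RLE (camera adjusted p = 0.00216, and adjusted p = 0.944 with an estimated correlation). With the block 30.5% of all genes were lower. Among the list nlp-24 changed by -2.95 ± 0.67 and nlp-31 by -2.81 ± 0.54. The like-named nlp-29 is in the epidermis list and changed by -2.57 ± 0.61, so these decreases need not concern neuronal peptides. Cytochrome P450 and UDP-glucuronosyltransferase genes were lower in 52 of 88 and higher in 0 with the block, against the same 30.5% lower of all genes (1 and 0 adjusted over the list alone). Their median was -1.34, or -0.88 under RLE (camera adjusted p = 5.09e-05, and adjusted p = 0.944 with an estimated correlation), with ugt-62 at -3.28 ± 0.51.

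Of 17 tested genes of the elongin, cullin and SOCS box list in dopamine TRAP, 0 passed adjusted over the list alone and 1 was higher and 3 lower with the block. With the block 30.5% of all genes were lower, so the 3 are no more than genes in general. The median of -0.01 turned to 0.56 under RLE (camera adjusted p = 0.412). The lower ones were elc-1 (-1.74 ± 0.67), vhl-1 (-1.66 ± 0.57) and elb-1 (-1.30 ± 0.50, adjusted p = 0.023 with the block). rbx-1, rbx-2, cul-5 and cul-2 changed by -1.21, -0.81, -0.37 and 0.48 and passed neither fit, as did rab-3, snb-1 and ges-1 at -0.26, 0.52 and -0.79. vit-6 changed by 1.81 ± 0.59 and passed only with the block (adjusted p = 0.00234). tph-1 was not listed, and mod-5 was listed in replicate 1 alone. Leaving out TRAP replicate 1, TRAP replicate 2, input replicate 1 or input replicate 2 gave 842, 212, 0 or 436 called genes by limma without a block. Of the genes named here 26, 14, 0 or 17 then gained a call.

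**Figure D3:**
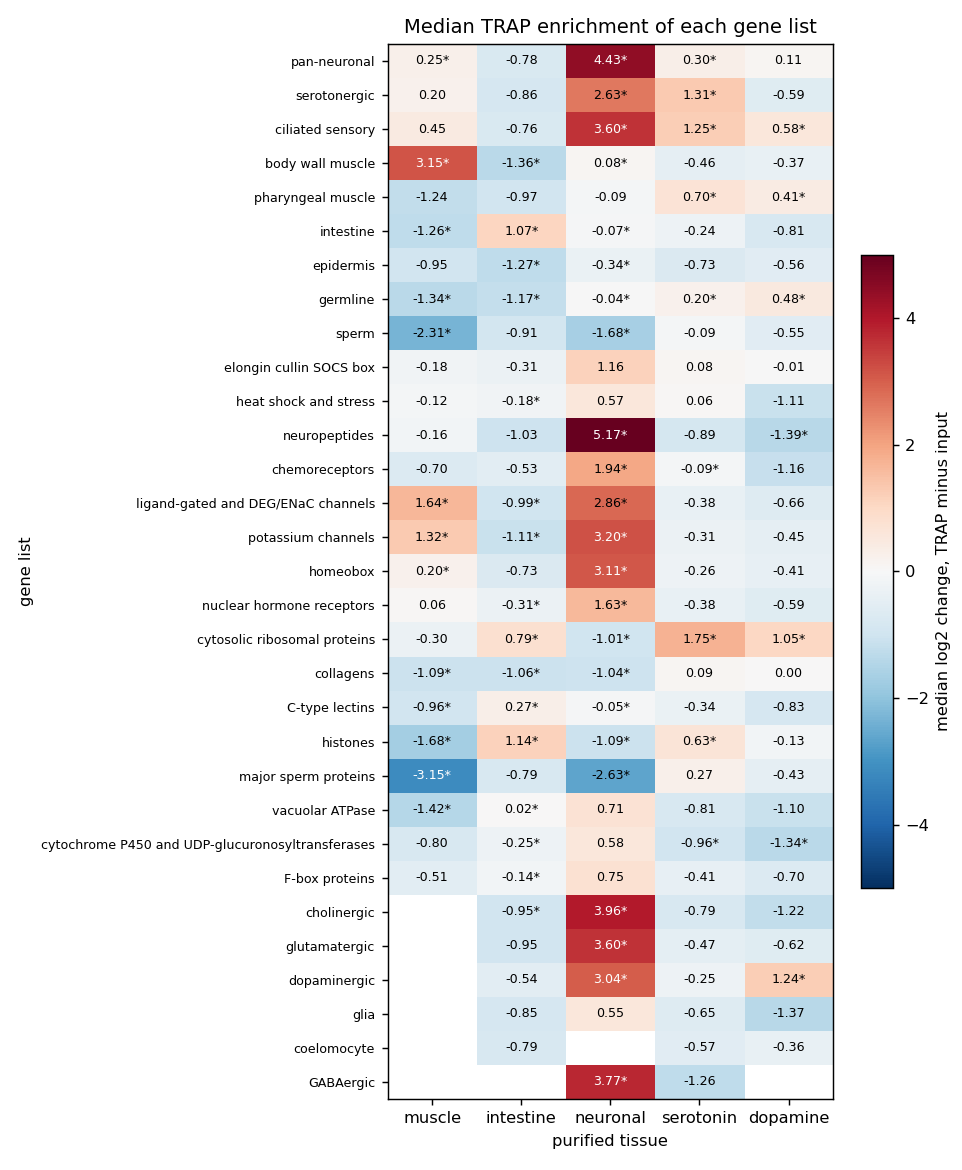
Median log2 change, TRAP minus input, of each gene list with at least 5 tested genes in each purification, red for higher in TRAP and blue for lower. An asterisk marks a camera adjusted p below 0.05 at the preset correlation. With an estimated correlation, a form that hardly any list could pass at 2 residual degrees of freedom, 0 lists passed in each purification. Body wall muscle was at 3.15 in muscle, intestine at 1.07 in intestine, pan-neuronal at 4.43 in neuronal, serotonergic at 1.31 in serotonin and dopaminergic at 1.24 in dopamine, all kept in sign under RLE. Signs turned under RLE for the elongin, cullin and SOCS box list in muscle, intestine and dopamine, ribosomal proteins and neuropeptides in muscle, heat shock genes in muscle, intestine and neuronal, body wall muscle in neuronal and dopamine, major sperm proteins in intestine and dopamine, sperm in serotonin and dopamine, chemoreceptors in intestine and serotonin, cytochrome P450 genes in intestine and neuronal, homeobox genes in serotonin and dopamine, dopaminergic, nuclear hormone receptor and F-box genes in intestine, glia and vacuolar ATPase in neuronal, intestine and potassium channels in serotonin, and epidermis, coelomocyte and histones in dopamine.

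The dopamine and serotonin purifications were compared directly, as the difference of their TRAP changes over 8 libraries. Only genes listed in both replicates of both purifications entered, so tph-1, cat-2 and mod-5 were not compared. limma called 0 of 14001 genes higher in dopamine and 0 higher in serotonin (155 at an unadjusted p below 0.05) and edgeR 0 and 0 (153 unadjusted). limma with the replicate as a block called 5 and 46 and DESeq2 8 and 27. Across genes the changes correlated at 0.854, where genes are not independent replicates. The 5 genes higher in dopamine with the block were flp-33 (difference 6.90 ± 1.67, SE, adjusted p = 0.00492 with the block), F59F3.6 (5.94 ± 1.15), F09E10.7 (5.77 ± 1.01), F58H7.1 (4.35 ± 1.28) and dat-1 (3.53 ± 1.12, adjusted p = 0.032 with the block). The largest of those higher in serotonin were R102.2 (-7.04 ± 0.97), C04E6.8 (-6.98 ± 1.03, adjusted p = 2.92e-05 with the block), Y41E3.5 (-6.92 ± 1.10), F28D1.6 (-6.47 ± 0.74), F45E12.6 (-5.71 ± 1.12), C33A12.4 (-5.03 ± 1.48), F58B4.3 (-4.997 ± 0.784) and R102.1 (-4.94 ± 0.82). R102.2 rose in serotonin TRAP with the block and stood in dopamine at 96.2 and 28.1 RPKM in TRAP against 128.4 and 180.1 in input. The differences of cat-1 (-0.98 ± 0.91), bas-1 (-1.09 ± 0.70), rpl-1 (-1.12 ± 1.21), rab-3 (-1.11 ± 0.90), unc-54 (0.69 ± 2.47), elb-1 (-0.28 ± 0.58), elc-1 (0.42 ± 1.22), cul-5 (-0.01 ± 0.71) and rbx-1 (0.56 ± 0.63) did not pass either fit. Without dopamine TRAP replicate 2, limma called 1 gene higher in dopamine, and without any other single library it called 0.

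Called genes were compared between purifications. Of the genes tested in each pair, muscle and neurons shared 9 higher genes where independent lists would share 8.31 (Fisher's exact test p = 0.717). Intestine and neurons shared 0 against 4.76 (Fisher's exact test p = 0.0126), and muscle and intestine shared 0 against 0.408. Between these 3 purifications lower genes were shared above that number, 53 against 0.686 between muscle and neurons (Fisher's exact test p = 2.28e-98). The count was 11 against 3.75 between muscle and intestine (Fisher's exact test p = 0.00118) and 9 against 3.27 between intestine and neurons (Fisher's exact test p = 0.00506). The test takes genes as independent, yet major sperm protein genes, near copies, were 27 of 95 lower calls in muscle and 26 of 79 in neurons. Under RLE limma called 15 genes lower in muscle and 0 either way in intestine, so none of these 3 lower counts can hold there. With the replicate block the excess between intestine and neurons was gone, at 17 lower genes against 16.9 (Fisher's exact test p = 1.00), and muscle and intestine shared 1.5 times the 79.3 lower genes that independent lists would share (Fisher's exact test p = 1.41e-06). With the block, serotonin and dopamine shared 762 higher genes against 99.7 and 3278 lower genes against 1289. Neurons shared 280 higher genes with serotonin against 155 (Fisher's exact test p = 1.28e-25) and 78 with dopamine against 105 (Fisher's exact test p = 0.00305). Intestine and serotonin shared 65 higher genes against 27.1 (Fisher's exact test p = 2.86e-11) and 1676 lower genes against 871.8. For higher genes that is fewer than neurons and serotonin shared but a larger ratio, 2.40 against 1.81, a difference that was not tested. Neurons shared fewer lower genes than independent lists would, 13 against 23.5 with serotonin (Fisher's exact test p = 0.00999) and 13 against 24.5 with dopamine (Fisher's exact test p = 0.00546). Muscle and neurons then shared 48 higher genes against 23.3. Of 9792 genes tested in all 5 purifications, 1 was higher in all of them with the block, lin-15A, and 5 were lower in all, msp-33, msp-64, msp-142, msp-152 and F23A7.8. These 6 names follow from the counts and, apart from F23A7.8 and msp-152, were chosen after their values were seen.

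**Figure D4:**
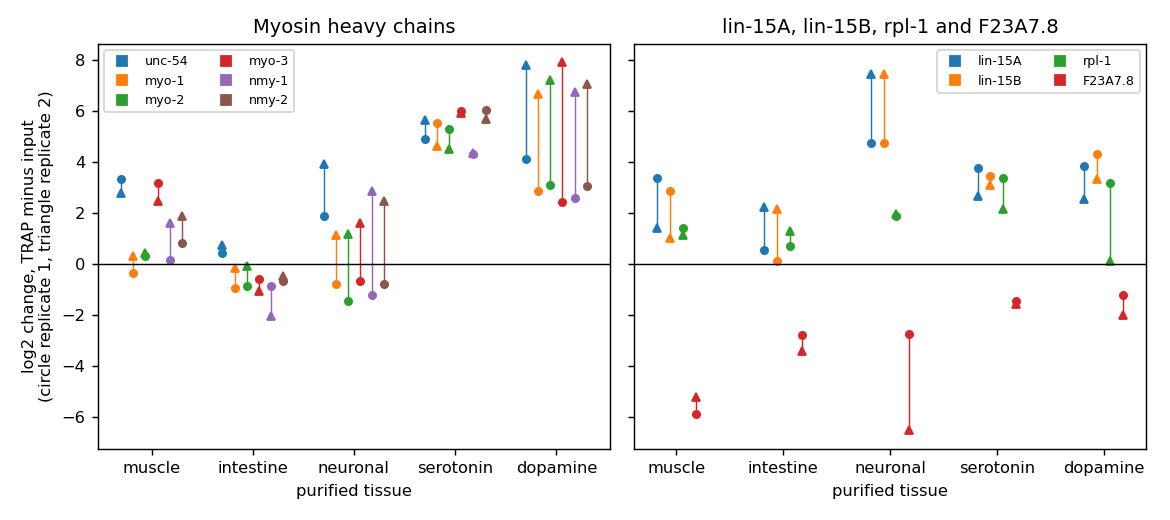
Log2 change, TRAP minus input, in each purification for 6 myosin heavy chain genes (left) and for lin-15A, lin-15B, rpl-1 and F23A7.8 (right), with circles for replicate 1, triangles for replicate 2 and a line joining them, drawn for genes chosen in part after their values were seen. The median of these 6 myosins was 2.96 and 7.14 in the dopamine replicates and 5.42 and 5.14 in the serotonin replicates, and the change of lin-15A was 2.40, 1.40, 6.11, 3.23 and 3.19 from muscle to dopamine.

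The authors' deposited tables also list enriched genes per purification, 577 for muscle, 719 for intestine, 2370 for neurons, 756 for serotonin and 564 for dopamine. Requiring a deposited ratio of at least 5 (muscle and neurons) or 2 (the others) in both replicates rebuilt every list exactly, once the 779 genes that met the rule in both serotonin and dopamine were taken out of those lists. As the lists were chosen on these libraries, their counts are not independent evidence of direction. Of the authors' listed genes, limma called 108 in muscle, 57 in intestine, 1984 in neurons, 0 in serotonin and 0 in dopamine. With the replicate block it called 269, 270, 1894, 579 and 323. DESeq2 called 569, 580, 2296, 538 and 372. By deposited RPKM, 332, 353, 2311, 633 and 363 of them kept the stated ratio in both replicates. The direct comparison held 415 of the 564 listed dopamine genes and 528 of the 756 listed serotonin genes. By limma 0 and 0 of them differed (11 and 80 at an unadjusted p below 0.05). With the block 5 and 40 did. In the authors' deposited table the top dopamine gene was flp-33, with ratios of 1154 and 22.4, and the top serotonin gene was srsx-29, with 623.0 and 18.4.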

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

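The comparisons of lists in this part, serotonergic, stress and chemoreceptor genes, were planned, and the tests of causes given under "Other observations" in part were not. For 3 gene lists both dopamine replicates lay on one side of 0 and both serotonin replicates on the other, and the difference was not tested. Serotonergic genes had a median log2 change of -0.59 in dopamine TRAP (-0.86 and -0.72 in the replicates, 14 genes tested) and 1.31 in serotonin TRAP (1.44 and 0.83, 21 genes tested). Heat shock and stress genes had a median of -1.11 in dopamine (-1.50 and -0.82, 13 genes) and 0.06 in serotonin (0.06 and 0.03, 15 genes). Chemoreceptor genes had a median of -1.16 in dopamine (-1.50 and -0.75, 25 genes). In serotonin (48 genes) their replicate medians were 0.14 and 0.09 while the median of the mean changes was -0.09, which turned to 0.23 under RLE. The 3 dopamine medians stayed below 0 under RLE, at -0.24, -0.50 and -0.65. Relative to the median of all genes in that purification, -0.60, they were 0.01, -0.51 and -0.56, so the serotonergic value is that of genes in general. Different numbers of genes were tested in the purifications, and no explanation of these differences was tested.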

How the results depend on the processing

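edgeR on recovered reads, RLE scaling of RPKM, their combinations with the block, and the block for the overlaps and the authors' lists were chosen after the data were seen, the other tests before. Given as higher and lower genes, the replicate block called 328 and 429 in muscle, 317 and 2935 in intestine, 1425 and 4236 in serotonin and 1216 and 4386 in dopamine, 5 and 46 in the dopamine to serotonin comparison, 269, 270, 579 and 323 of the authors' muscle, intestine, serotonin and dopamine genes, and overlaps of 4 (muscle and intestine), 48 (muscle and neuronal), 15 and 14 (muscle with serotonin and dopamine), 7, 65 and 14 (intestine with neuronal, serotonin and dopamine), 280 and 78 (neuronal with serotonin and dopamine) and 762 (serotonin and dopamine). DESeq2 called 913 and 221 in muscle, 701 and 280 in intestine, 1013 lower in neuronal, 1304 and 936 in serotonin, 1265 and 799 in dopamine, 8 and 27 in the comparison, and 569, 580, 538 and 372 of the authors' genes. RLE scaling gave 288 and 15 in muscle, 0 and 0 in intestine and 1383 higher in neuronal, and with the block 1292 and 996 in muscle, 1852 higher in intestine, 2051 lower in neuronal, 2584 and 2963 in serotonin and 2678 and 2488 in dopamine. edgeR gave 320 and 14 in muscle and 0 and 0 in intestine and neuronal, and with the block 1298 and 503 in muscle, 1726 higher in intestine, 1318 lower in neuronal, 2458 and 2505 in serotonin and 1932 and 1916 in dopamine. The joint fit gave 224 higher in muscle, 0 and 0 in intestine, 4 higher in serotonin, 59 and 136 in dopamine and 1 higher in serotonin in the comparison, where TRAP against TRAP without the inputs gave 18. A pseudocount of 0.1 gave 22 and 377 in intestine, a pseudocount of 5 gave 54 lower in muscle, 33 and 437 in intestine and 1030 and 33 in neuronal, and a mean RPKM of at least 5 gave 5 and 115 in intestine. With an estimated correlation 0 lists passed in each tissue, against 13, 16, 23, 9 and 7 from muscle to dopamine. With 2 residual degrees of freedom hardly any list could pass that form, so the 0 decides nothing about the lists. Leaving out 1 library gave 15 to 219 higher and 4 to 1785 lower in muscle, 6 to 124 and 49 to 1255 in intestine, 457 to 4024 and 5 to 135 in neuronal, 0 to 156 and 0 to 686 in dopamine and 0 to 1 higher in dopamine in the comparison, the lone library of a group being assumed to vary like the others. The cause was not tested. Overlaps at a fold of at least 2 and counts with no filter stayed within 1.5 times.

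Of 4415 values of 298 gene results under the alternatives, 3261 kept direction and side of the threshold, 430 no longer passed, 517 newly passed, 207 changed sign without passing before or after and 0 changed sign with a call. The alternatives that apply to counts in edgeR (library totals, count filters) were not run, as the main test used RPKM. The neuronal inputs had the lowest medians, 44 and 70 reads per listed gene, which in replicate 2 is not from depth alone, as it had 31.5 M reads.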

Other observations

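Chosen only after the results were seen were the tests of muscle RNA and of shared paralog reads for the myosins, of pseudogenes among the shared genes, of rpl-1 for lin-15, of the myosin reads against all genes for the ribosomal protein genes and of the share called lower for the non-coding RNAs, while the other tests here were written first. In neuronal TRAP, 63 of 77 chemoreceptor genes were higher and 0 lower (66 higher adjusted over the list alone), at a median log2 change of 1.94, or 1.53 under RLE (camera adjusted p = 8.05e-16, and adjusted p = 0.53 with an estimated correlation). Collagen genes, which build the cuticle, had a median of -1.04 in neuronal TRAP, or -2.17 under RLE, and of -1.90 and -0.18 in its replicates (0 called by limma, camera adjusted p = 1.2e-20, and adjusted p = 0.53 with an estimated correlation). In dopamine TRAP with the replicate block, the stress genes gst-4, hsp-12.6 and sod-3, for a glutathione transferase, a small heat shock protein and a superoxide dismutase, were lower by log2 changes of -2.62 ± 0.66, -1.69 ± 0.68 and -1.39 ± 0.44, none of them called without the block. Of the 13 tested genes of their list 5 were lower and 0 higher with the block, near the 4386 of 14400 lower among all genes (camera adjusted p = 0.311). gst-4 and hsp-12.6 were lower in serotonin TRAP too with the block, by -2.12 ± 0.41 and -1.07 ± 0.53.

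The myosin heavy chain genes unc-54, myo-1, myo-2, myo-3, nmy-1 and nmy-2, chosen as a set after their values were seen, had log2 changes of at least 4.67 in dopamine TRAP and 4.34 in serotonin TRAP, against 3.84 and 3.16 for myo-5 and 0.51 and 0.36 for myo-6, which are not in the set. The 6 took 0.434% and 27.7% of the reads of dopamine TRAP replicates 1 and 2 and 1.98 and 1.72% of the serotonin ones. RNA from muscle cells would raise the other body wall muscle genes too, and their median in dopamine was -0.4545 with an upper quartile of 0.21, far below the myosins although the whole list's median of -0.37 turned to 0.24 under RLE. Long transcripts in general do not reach the myosins either, as other genes at least as long had an upper quartile of 1.151. Reads shared between the paralogs would hold each at a fixed share of unc-54. The smallest ratio of a share in dopamine TRAP to the smallest share in any TRAP library was 2.62. That smallest share is from a single library. For nmy-1 and nmy-2 it was muscle TRAP replicate 1 (0.3548 and 0.5113%), while muscle TRAP replicate 2 had 3.405 and 8.876%. A first form of that test, against the muscle purification, gave 0.614 and left the point open, and the second form was written after that result. As the shares differ this much between the muscle replicates, shared reads stay open. No biological explanation was tested.

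Dopamine and serotonin TRAP shared 762 higher genes with the block. If they were transcripts common to neurons they should be called in neuronal TRAP more often than other genes, but 6.05% were (43 of 711), against 10.2% (1245 of 12233) of all genes (Fisher's exact test p = 9.0e-05). Their median length was 1.23 times that of all genes (1.15 to 1.32 by bootstrap). The whole range lies below the ratio that the prediction written first asked for if length were the cause. The 1.23 also meets its bound against length, but the range passes that bound, which leaves length open. Pseudogenes made up 10.9% of them against 2.68% of all genes, 4.07 times the share (Fisher's exact test p = 3.9e-29), so reads from pseudogenes or genomic DNA may contribute. The shared genes were low, with a median dopamine input of 7.284 RPKM against 17.9 for all genes. Neither the pseudogene share nor the share called in neuronal TRAP was matched for level, so level may lie behind both. A biology shared by the 2 neuron classes stays open and was not tested.

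From muscle to dopamine the log2 changes were 2.40 ± 1.09, 1.40 ± 0.60, 6.11 ± 1.02, 3.23 ± 0.76 and 3.19 ± 0.60 for lin-15A and 1.95 ± 1.23, 1.12 ± 0.62, 6.09 ± 1.09, 3.28 ± 0.54 and 3.83 ± 0.58 for lin-15B, genes chosen after their values were seen. Without the block both passed only in neuronal (adjusted p = 3.69e-07 and 2.49e-06), and with it lin-15A passed in all 5 but lin-15B neither in muscle nor in intestine (adjusted p = 0.192 and 0.0904). lin-15 is in common use as a marker for transgenes, and a candidate explanation is transgenes that carry lin-15 beside the tagged ribosomal protein gene rpl-1, although the labels name neither. rpl-1 had the largest change of the 80 ribosomal protein genes in 2 of 5 tissues, which decides nothing. Higher capture of synMuv transcripts in general is argued against, as the upper quartile of the other synMuv genes lay below both lin-15 genes in 5 of 5 tissues.

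The ribosomal protein genes lay on opposite sides in the dopamine replicates, with replicate 1 minus replicate 2 at 1.861 in TRAP and -1.355 in input. Other genes of that length showed 9.24% of the difference between the replicates, so short transcripts in general do not account for it. Leaving the myosin reads out of the totals left the replicate 2 median at -0.3287, and the difference between the replicates stayed 3.502 above that of all genes (quartiles 2.918 and 4.317), so reads taken up by the myosins, which would move all genes alike, do not account for it either. Of annotated non-coding RNAs, limma called 24 lower and 1 higher of 176 in muscle, 60 and 1 of 217 in intestine and 19 and 55 of 229 in neuronal. That is 13.6, 27.6 and 8.3% lower, against 0.945, 5.34 and 0.588% of all genes and 1.86, 4.07 and 1.23% of coding genes of the same length range (Fisher's exact test p of 1.53e-12, 8.44e-30 and 1.41e-09). Under RLE limma called 15 genes of any kind lower in muscle and 0 in intestine, so the 24 and 60 lower calls cannot hold under that scaling. With the block the excess held in muscle, intestine and neuronal but turned in serotonin and dopamine, at 38 of 232 and 44 of 250 lower against 42.4 and 46.7% of those coding genes. The non-coding median minus that of these coding genes was -0.25 in muscle and -0.28 in intestine, and 0.47, 0.94 and 1.15 in neuronal, serotonin and dopamine. It lay within 0.5 of, or above, them in 5 tissues. By the prediction written first, that counts against RNAs without bound ribosomes being left behind. The prediction was set aside because in neuronal, serotonin and dopamine the members went both ways, a condition it did not hold. The excess of lower calls in muscle and intestine without RLE goes the other way, so the explanation is left open here. The non-coding median lay more than 0.5 below that of these coding genes in 0 tissues, which leaves short transcripts in general open too.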
